A study of Homo sapiens with 2 samples.

How the data were processed

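The study measured mature microRNAs (miRNAs) in CL1-5 cells, a highly invasive human lung adenocarcinoma line, by quantitative reverse-transcription PCR. There was 1 sample from cells carrying the empty expression vector pcDNA3.1 (the control) and 1 from cells made to overexpress ANGPTL1, a secreted angiopoietin-like protein. Per the labels' protocols, stably expressing cells were selected with the antibiotic G418 for 4 weeks, 500 ng of total RNA entered a multiplexed reverse transcription with assay-specific primers, and PCR ran for 40 cycles on a TaqMan Low Density Array card, Human MicroRNA Panel version 1.0. The groups were taken from the treatment label of each sample. With 1 sample per group there was no replicate spread, so no test, p-value or standard error is given for any difference between the samples, and every difference compares these 2 RNA samples rather than the conditions in general.

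The deposited data were 3 tables, of which the first held 366 assays, 365 for miRNAs and 1 for the small nucleolar RNA RNU48, the endogenous control; the others gave values for the 365 miRNA assays. This first table gave the average threshold cycle (Ct) of each assay, per the file headers. The Ct is the PCR cycle at which fluorescence crosses a set level, so an assay with 1 cycle less holds about 2 times the template, assuming that each cycle doubles it. The number of wells averaged, their spread, the threshold setting and the software are not given in the sources used here. No cell was blank, and a value of 40, the last cycle, was read as no amplification. The second table held delta Ct, the Ct of the assay minus the Ct of RNU48 in the same sample, per the file headers, and these values differed from the difference of the deposited cycles by at most 0.01. The third table held the authors' deposited fold change, the ratio of ANGPTL1 cells over control cells, which equalled 2 to the power of minus delta delta Ct within 1.8e-07 on the log2 scale. In the delta Ct table, 2 further columns of relative levels repeat delta Ct on a linear scale and were not used here.

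The log2 ratio of each miRNA was computed as delta Ct in the control minus delta Ct in ANGPTL1 cells, so that positive values mean more miRNA in ANGPTL1 cells relative to RNU48. A miRNA counted as detected below cycle 35. Ratios were counted and ranked only for miRNAs detected in both samples, and a miRNA counted as higher or lower where the ratio was at least 2-fold. For a miRNA detected in 1 sample alone, the later Ct was set to 35 and the result is printed as "at least". For 3 miRNAs detected in the control alone, the bound lay above 0 and gives no direction. Setting a cycle above 35 to 35 understates the difference, and the deposited fold changes, which use the cycles up to 40, are larger. For an assay at 40 in both samples the deposited log2 ratio is 0.42, the difference of the RNU48 cycles alone, and is not a measurement of that miRNA.

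The threshold cycle, the fold rule, 17 groups of miRNAs, 7 lists of marker miRNAs of other cell types and the rule for named miRNAs were fixed before the data were examined. Named were the 12 largest increases and 12 largest decreases among miRNAs detected in both samples, up to 5 detected in only 1 sample for each sample, the 5 with the lowest Ct in the control, miR-630, RNU48, and up to 4 members of each list. MiRNAs named beyond this rule were chosen after their values were seen. Assay names were matched to lists by spelling. A total of 14 names stood on 2 assay numbers each (28 assays), and the name leaves open which arm of the hairpin each assay reads. Such assays entered a list only where the list held both arms. This rule, the cycle of 35 as a bound and the view of the 14q32 cluster over at least 1 sample were chosen after the data were seen. A planned list entry gave miR-378 and miR-422b as spellings of 1 assay; both were on the card, and the list took miR-378.

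For each list with at least 3 members detected in both samples, the median log2 ratio was set against the medians of 10000 random lists of the same size drawn from the detected miRNAs and matched on 5 bins of mean Ct. The percentile describes these 2 samples and is not a p-value, and it does not depend on the reference RNA. The percentile was tried on simulated data with the level-dependent spread of the 145 detected miRNAs. Lists of 9 with no shift reached the top 2.5% of matched lists in 1.0% of 100 simulations. Lists shifted by 1 log2 unit did so in 95.0%. These lists were drawn at random from miRNAs detected in both samples. The rates need not hold for lists whose members vary together, such as neighbouring genes, or for lists that hold bounds. With no shift, 5.3% of single simulated miRNAs passed the 2-fold rule in the upward direction, and 94.4% did so with a shift of 2 log2 units. The simulated spread was that of the observed ratios, which holds real differences as well as noise, so 5.3% is not a rate of false calls.

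The alternatives were RNU48 recomputed from the cycles, the global median of detected miRNAs as reference, no normalization, detection limits of 32, 38 and none, thresholds of 1.5-fold and 4-fold, and the authors' fold change table. RNU44 and RNU6B as references were planned and not run, since RNU48 is the only control among the assays used here, and the mean of the controls is then RNU48 alone. Robust SDs are 1.4826 times the median absolute deviation. Which miRNA genes lie next to each other was taken from the RefSeq annotation of GRCh38.p14, which gave 1 gene for 286 assays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.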

Results

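Mature miRNAs were profiled in CL1-5 lung adenocarcinoma cells carrying the empty vector and in CL1-5 cells overexpressing ANGPTL1, with 1 RNA sample of each. RNU48 crossed threshold at cycle 20.79 in the control and 21.21 in ANGPTL1 cells. Of 365 miRNA assays, 157 were below cycle 35 in the control and 158 in ANGPTL1 cells, and 155 and 153 stood at cycle 40. A total of 145 miRNAs were detected in both samples, 12 in the control alone, 13 in ANGPTL1 cells alone and 195 in neither. The earliest cycles in the control belonged to miR-222, followed by miR-594 at cycle 20.73, miR-16 at 21.48, miR-92 at 22.04 and miR-93 at 22.20. Relative to RNU48, miR-222 and miR-16 were 1.28-fold lower in ANGPTL1 cells, miR-92 was 1.04-fold lower, miR-594 was 1.75-fold lower and miR-93 was 2.3-fold lower. There are no replicates, so no difference carries an error, and ANGPTL1 itself was not measured on the card.

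The main comparison asked which miRNAs differ between ANGPTL1-overexpressing and vector control cells. Among the 145 miRNAs detected in both samples, 11 were at least 2-fold higher in ANGPTL1 cells, 7 were at least 2-fold lower, and 127 (87.6%) lay within 2-fold. The largest difference upward was that of miR-155, a miRNA known from immune activation, which crossed threshold at cycle 31.34 in the control and 28.18 in ANGPTL1 cells, a log2 ratio of 3.58 relative to RNU48. miR-127, encoded in the imprinted 14q32 region, was 8.22-fold higher. miR-146a, which is induced by NF-kappaB and represses TRAF6 and IRAK1, was 4.44-fold higher, and miR-34c, a p53-induced miRNA, was 4.11-fold higher. let-7b was 3.68-fold higher and miR-200c, a repressor of the epithelial-mesenchymal transition factors ZEB1 and ZEB2, was 3.53-fold higher. The others past 2-fold on the higher side were let-7c (2.19-fold), miR-30a-5p (2.17-fold), miR-130a (2.16-fold), miR-22 (2.13-fold) and miR-7 (2.11-fold), and miR-589 followed at 1.84-fold.

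The largest difference downward was that of miR-486, a miRNA abundant in red blood cells, at cycle 28.75 in the control and 32.75 in ANGPTL1 cells, a log2 ratio of -3.58. miR-422b was 7.01-fold lower and miR-422a 2.23-fold lower. miR-183 was 2.93-fold lower, and miR-93 was 2.3-fold lower, miR-139 2.19-fold and miR-107 2.06-fold. The next were miR-330, with a log2 ratio of -0.96, miR-565 (-0.87), miR-622 (-0.85), miR-594 (-0.81) and miR-15a (-0.79), none of them past 2-fold. For miR-565 and miR-594, the RefSeq annotation of GRCh38.p14 lists no miRNA gene under that name. At a stricter 4-fold size, miR-155, miR-127, miR-146a and miR-34c remained on the higher side and miR-486 and miR-422b on the lower side. Of these, only miR-155 was below cycle 32 in both samples. In the control miR-127 stood at cycle 33.66, miR-146a at 32.38 and miR-34c at 34.46. In ANGPTL1 cells miR-486 stood at cycle 32.75 and miR-422b at 32.59. A detection limit of 32 therefore leaves out all of them but miR-155.

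The cycles of the 145 miRNAs correlated across miRNAs, which are not independent replicates, with Pearson's r = 0.971 and Spearman's rho = 0.966. The median log2 ratio was -0.01, with a 95% order-statistic interval over miRNAs, not over samples, of -0.09 to 0.09. The robust SD of the log2 ratios was 0.52 for miRNAs with a mean cycle below 25, 0.34 from 25 to 28, 0.42 from 28 to 30, 0.68 from 30 to 32 and 0.92 for the latest 12 miRNAs below 35. Without the RNU48 reference every log2 ratio was lower by 0.42, and the split of miRNAs past 2-fold was then 6 higher and 29 lower. All directions given here are relative to RNU48.

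**Figure D1:**
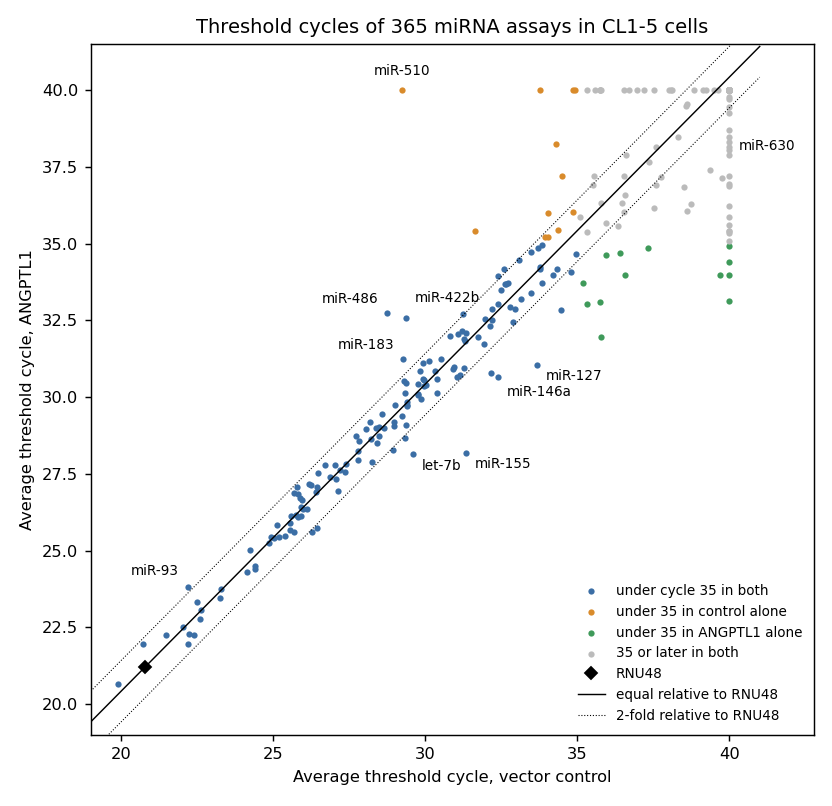
Average threshold cycle of each of the 365 miRNA assays in the control (x axis) and in ANGPTL1 cells (y axis), in PCR cycles, coloured by detection below cycle 35; the solid line marks equal levels relative to RNU48 and the dotted lines 2-fold differences, and later cycles mean less miRNA. Of the 145 assays detected in both samples 127 lie between the dotted lines, with miR-155 and miR-127 farthest below them and miR-486 and miR-422b farthest above.

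Of the miR-200 family and miR-205, miR-200c was detected in both samples and the other 4 measured members with settled names in neither; miR-141, its neighbour in the genome, stood at cycle 40 in the control and 35.40 in ANGPTL1 cells, later than the limit. Of the miR-30 family, which represses SNAI1, 4 of 5 members were detected in both samples with a median log2 ratio of 0.32, or -0.10 without normalization, at percentile 94.7 of matched random lists. With a detection limit of 38 or none, where miR-30e-5p entered as the fifth member, the median was 0.04. Its members ranged from 0.03 (miR-30c) and 0.04 (miR-30b) through 0.61 (miR-30d) to 1.12 (miR-30a-5p). miR-30e-5p was detected in the control alone. Among miRNAs with SNAI2 as a described target, miR-203 had a log2 ratio of -0.30, miR-33 was detected in the control alone and miR-218 in ANGPTL1 cells alone, and 2 further members in neither sample.

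The motility-suppressing group had a median log2 ratio of 0.50 over 6 detected members, at percentile 95.4, and 0.08 without normalization. With a limit of 38 or none it was 0.84. In it miR-146a (2.15) and miR-7 (1.08) were past 2-fold on the higher side, miR-146b stood at 0.84, and miR-101 at -0.78. The motility-promoting group had a median of -0.29 (-0.71 without normalization) over 5 members, at percentile 11.2, while its mean was 0.38 because of miR-155. Apart from miR-155 it held miR-107 (-1.04), miR-21 (-0.42), miR-210 (-0.29) and miR-103 (0.06), and its median was -0.12 with each of the other detection limits. The angiogenesis-linked group had a median of -0.29 (-0.71 without normalization) over 7 members, at percentile 6.5, and a mean of -0.06. In it miR-130a stood at 1.11 and miR-296 at -0.60, and miR-218 was detected in ANGPTL1 cells alone. The planned entry naming miR-378 and miR-422b took miR-378 (-0.44), so the median and mean leave out miR-422b (-2.81).

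let-7 miRNAs, which repress RAS and HMGA2, had a median log2 ratio of 0.46 over all 8 members measured, at percentile 97.6 of matched lists. Of these members 7 lay above 0 relative to RNU48 and 4 without normalization, where the median was 0.04. let-7b (1.88) and let-7c (1.13) were past 2-fold, and let-7d (0.80) and let-7f (0.68) were not. let-7c was close to the detection limit, at cycle 34.79 in the control and 34.08 in ANGPTL1 cells. Whether let-7 assays read each other's similar sequences was not tested. let-7g, named after its value was seen, was at -0.09. In the p53-induced miR-34 family, miR-34c was 4.11-fold higher in ANGPTL1 cells. miR-34b, which is transcribed with miR-34c, was detected there alone, at cycle 33.96 against 40 in the control, and was at least 2.75-fold higher. miR-34a, from another gene, had a log2 ratio of -0.17.

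In the growth-related polycistrons most members lay within 2-fold. The polycistron of miR-17 to miR-92 with its paralogs had a median log2 ratio of 0.00 (-0.42 without normalization) and a mean of -0.13 over 10 members, at percentile 36.9, and only miR-93 (-1.20) was past 2-fold. Its cluster partners miR-25 and miR-106b stood at -0.62 and -0.34. The family of miR-15 and miR-16 had a median of -0.14 (-0.56 without normalization) over 6 members at percentile 22.1, all within 2-fold. The clusters of miR-23, miR-27 and miR-24 had a median of 0.18, or -0.24 without normalization, over 5 members at percentile 71.0, all within 2-fold. miR-221 (0.25) and miR-222 (-0.36), as well as miR-29a (-0.05) and miR-29c (-0.26), were within 2-fold. In the cluster of miR-183 and miR-96, miR-183 had a log2 ratio of -1.55, and miR-96 was detected in the control alone, at least 1.46-fold lower in ANGPTL1 cells. An assay named miR-182 (number 4373271), of the same cluster but with an unsettled arm, was at -0.35. In the miR-181 family miR-181d was at -0.25, and miR-181b, at cycle 35.77 in the control and 31.95 in ANGPTL1 cells, was at least 11.1-fold higher. Percentiles were computed for 9 groups, and none is adjusted for that number.

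**Figure D2:**
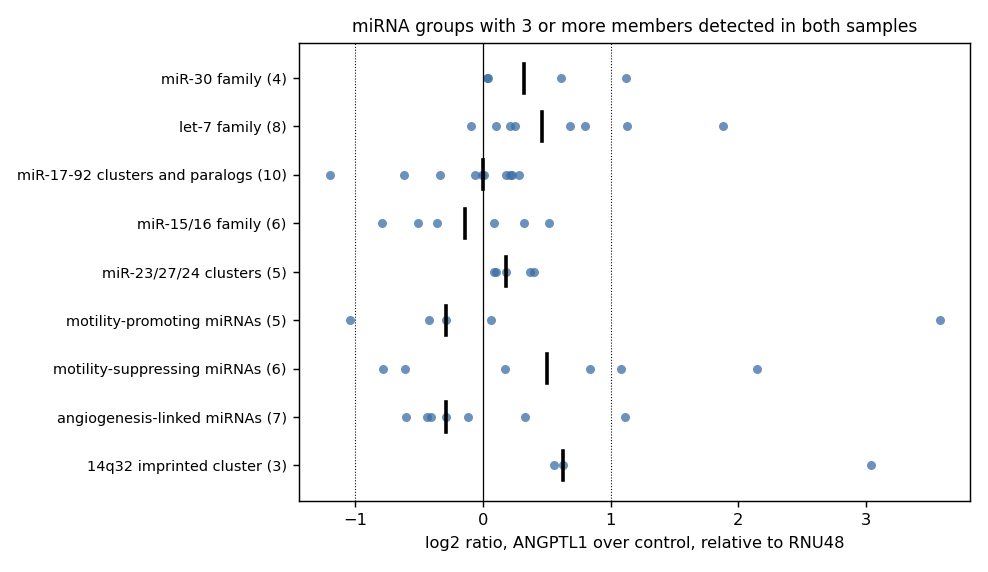
Log2 ratio of ANGPTL1 cells over control, relative to RNU48, for the 9 miRNA groups with at least 3 members detected in both samples; each point is 1 miRNA, the black bar is the median of the group, the number in brackets counts its members, and dotted lines mark 2-fold. Of the let-7 points 7 of 8 lie to the right of 0 (4 without normalization), with let-7b at 1.88, and the motility-promoting group holds miR-155 far to the right of its other members.

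The miRNAs of the imprinted 14q32 cluster were scarce, and 5 of the 9 detected in at least 1 sample were at least 2-fold higher in ANGPTL1 cells. Of 31 members that the list could take from the card, 3 were detected in both samples, and these had log2 ratios of 3.04 (miR-127), 0.63 (miR-134) and 0.56 (miR-380-3p). Their median of 0.63 lay at percentile 91.1 of matched lists, and was 0.21 without normalization, 1.19 with a limit of 38 and 1.94 with none. A further 6 members were detected in ANGPTL1 cells alone and 0 in the control alone. These, named after their values were seen, were an assay named miR-432 (number 4373280, at least 4.92-fold higher), miR-485-3p (at least 2.73-fold), miR-410 (at least 2.71-fold), miR-411 (at least 2.01-fold), miR-382 (at least 1.74-fold) and miR-487b (at least 1.66-fold). Taking all 9 members detected in at least 1 sample, a view added after the data were seen, the median log2 ratio was 1.01 and lay at percentile 99.33 of matched lists of other miRNAs. For the 6 detected in ANGPTL1 cells alone a bound above 0 follows from their detection there. Of the 9 ratios or bounds 4, those of miR-382, miR-487b, miR-134 and miR-380-3p, were under 2-fold. Of 161 other miRNAs detected in at least 1 sample, 69 had a ratio above 0. A further 7 were detected in ANGPTL1 cells alone, together 76 (47.2%), and 12 in the control alone. These 7 include an assay named miR-376a (number 4373026), a name on the 14q32 list that was left out for its unsettled arm. The other assay of that name (number 4378104) went the other way, at cycle 36.69 in the control and 40 in ANGPTL1 cells. The other assay named miR-432 (number 4378076) stood at 36.56 in the control and 36.58 in ANGPTL1 cells. Among the 22 members at cycle 35 or later in both samples, 15 stood at 40 in both, 4 were earlier in ANGPTL1 cells and 3 earlier in the control. The other large cluster of scarce miRNAs, the placental C19MC cluster, had 1 of 32 members detected, miR-517c in ANGPTL1 cells alone. Of the 32 members, 20 stood at cycle 40 in both samples, 4 were earlier in ANGPTL1 cells and 8 earlier in the control.

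**Figure D3:**
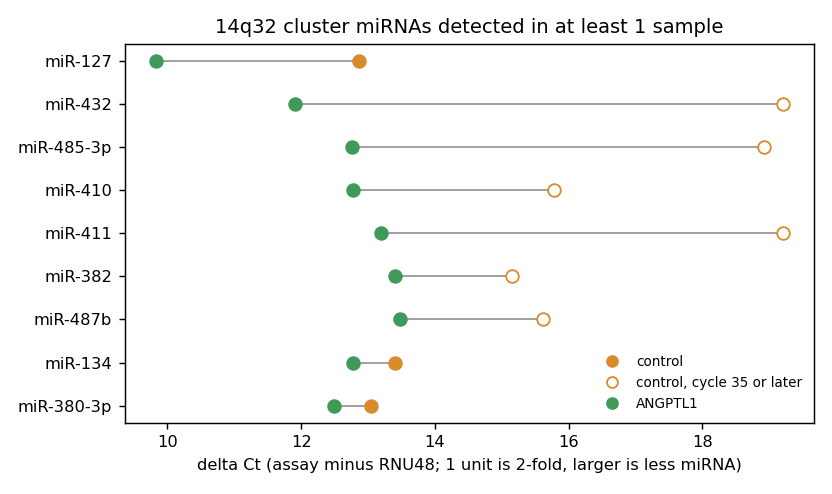
Delta Ct (assay minus RNU48, in cycles; larger values mean less miRNA) of the 9 members of the 14q32 cluster detected below cycle 35 in at least 1 sample, in the control and in ANGPTL1 cells. Open circles are control values from assays at cycle 35 or later, which give only a bound; in all 9 the ANGPTL1 value lies to the left, from 0.56 cycles for miR-380-3p to 3.04 for miR-127 among those measured on both sides.

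A set of 8 miRNAs was detected in 1 sample and stood at cycle 40 in the other, 4 in each direction. The strongest was miR-510, at cycle 29.25 in the control and 40 in ANGPTL1 cells, at least 40.2-fold lower in ANGPTL1 cells; the authors' deposited table gives a 1287-fold difference. The others in the control alone were miR-33, miR-302c (assay 4373277) and miR-215, and those in ANGPTL1 cells alone were miR-432 (assay 4373280), miR-34b, miR-411 and miR-517c. Outside the naming rule, miR-302c, miR-215, miR-411 and miR-517c were named after their values were seen. Counting also miRNAs with a late cycle in the other sample, miR-95 was at least 7.73-fold lower in ANGPTL1 cells, and miR-449b at least 1.55-fold lower. An assay named miR-376a (number 4373026) was at least 5.24-fold higher, miR-137 at least 4.96-fold and miR-193b at least 3.29-fold.

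miR-630 is the miRNA that the study is known to have followed up, with SNAI2 (SLUG) as its target, so its place here is not independent evidence. It stood at cycle 40 in the control and 38.16 in ANGPTL1 cells, later than the detection limit in both samples. The authors' deposited table gives 4.79-fold, which rests on the value of 40 in the control. By that same source, 29 miRNAs had a fold change at least as high in the authors' deposited table, miR-630 included, 17 of them at cycle 35 or later in both samples. A total of 21 miRNAs, miR-630 among them, stood at 40 in the control and between 35 and 40 in ANGPTL1 cells, and 19 showed the reverse. A difference in miR-630 was not detectable at this depth.

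Marker miRNAs of other cell types were mostly undetected. Of blood cell markers, miR-142-3p was detected in the control alone, at cycle 34.51, and the other 3 in neither sample. Of muscle markers only miR-133b was detected, at -0.55, and of fibroblast and smooth muscle markers only an assay named miR-199a (number 4378068), at -0.70. The 2 assays named miR-126, an endothelial miRNA, were at 0.33 and -0.41. They were well detected, at cycles 29.86 and 25.87 in the control. The liver marker miR-122a and 4 pluripotency markers with settled names were detected in neither sample, while an assay named miR-302c (number 4373277), with an unsettled arm, was at cycle 34.87 in the control and 40 in ANGPTL1 cells. Of neuronal markers, the 2 assays named miR-9 were at -0.75 and -0.63, miR-137 was detected in ANGPTL1 cells alone, and the other 3 in neither. The miR-9 assays were also well detected, at cycles 25.70 and 30.11 in the control.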

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

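The alternatives for the 14q32 cluster over at least 1 sample, and the largest single differences without normalization, were added after the data were seen. The number of miRNAs at least 2-fold higher (11) or lower (7) was the same with RNU48 recomputed from the cycles, with the global median as reference and with the authors' fold change table, which by construction repeat the ratios or shift all of them by 0.01 and so test little. Without normalization the counts were 6 and 29 and the median log2 ratio was -0.43. Detection below cycle 32 gave 6 higher and 2 lower, and below 38 gave 23 and 11. No limit gave 29 and 12, with assays at cycle 40 in either sample still left out. Fewer or more assays were then counted. A 1.5-fold threshold gave 24 and 28, and a 4-fold threshold 4 and 2. The count of miRNAs detected in 1 sample and at 40 in the other, 8 below cycle 35, was 1 below 32 and 30 below 38. Other limits count fewer or more assays, and without normalization each ratio is lower by 0.42, the difference in RNU48. The median of the 14q32 members detected in at least 1 sample was 3.02 with the deposited cycles up to 40 instead of 35 as a bound, and from 0.59 to 1.38 under the other alternatives. Below cycle 32 only 1 member was left, at percentile 91.16, and with miR-432 left out the percentile was 98.52. Every group median is lower by 0.42 without normalization, and those of the miR-30 family (-0.10) and of the clusters of miR-23, miR-27 and miR-24 (-0.24) turned negative. With other detection limits the medians of the miR-30 family, both motility groups and the 14q32 cluster differed by more than 1.5 times. The 24 largest differences kept their sign without normalization. Increases of 0.88 or more cannot change sign when lowered by 0.42, nor can decreases, so this tests little. RNU44 and RNU6B as references were not run, and no replicate could be left out. No paired analysis was possible because each group has 1 sample. The robust SD of log2 ratios over miRNAs was 0.52 below cycle 25, 0.34 from 25 to 28 and 0.92 for the 12 latest miRNAs below 35; it holds real differences as well as noise, which 1 sample per group cannot separate.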

Other observations

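The tests of explanations in this part were chosen after the ratios of single miRNAs had been seen, and only the percentile of the 14q32 members detected in both samples was planned. MicroRNAs encoded next to each other and often cut from 1 transcript had, in the median over pairs, closer log2 ratios than shuffled pairs. On chromosome X, the members miR-362 (-0.49), miR-501 (-0.67), miR-502 (-0.31), miR-532 (-0.47) and miR-660 (-0.22) of 1 cluster all had ratios below 0, as had miR-500 (-0.21), relative to RNU48 and without it; relative to RNU48 all were within 2-fold. miR-125a (0.32), miR-99b (0.22) and let-7e (0.10), another set of neighbours, lay together slightly above 0, and below 0 without normalization. Over 34 pairs of genes within 10 kb, formed by 37 miRNAs detected in both samples, the median absolute difference between neighbours was 0.29 on the log2 scale. Many of these pairs came from the cluster of miR-17 to miR-20a and from that on chromosome X, whose members enter several pairs each. Shuffling the ratios within bins of threshold cycle gave a median of 0.55, and 0.73% of 10000 shuffles gave a difference as small. Independent noise of single assays would leave neighbours no closer than shuffled pairs, so it does not account for all of the variation between these 37 miRNAs. Whether this holds without the clusters that give many pairs was not tested. Similar sequences read by each other's assays may add to the likeness of some pairs, which was not tested. Some neighbours did part, such as miR-424 (-0.51) and miR-503 (0.71), or miR-183 (-1.55) and an assay named miR-182 (-0.35). Likewise miR-224 was at 0.64 and an assay named miR-452 at -0.26. The 5 pairs of assays matched by name to 1 hairpin differed by a median of 0.38 and at most 0.91. Matching by name did not pair miR-378 (-0.44) with miR-422b (-2.81), which a planned list gave as spellings of 1 assay.

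The 14q32 cluster as a group stands out because 6 members were detected in ANGPTL1 cells alone and 0 in the control alone. Among the other miRNAs the counts were 7 and 12. Those 7 include an assay named miR-376a (number 4373026), which the 14q32 list names but could not take. The other assay of that name (number 4378104) was late in both samples and earlier in the control. Of the 22 members late in both samples, 4 were earlier in ANGPTL1 cells and 3 in the control. Fibroblasts or smooth muscle cells mixed into the ANGPTL1 sample would bring miR-143, miR-145, miR-199a, miR-199b and miR-214, and 0 of their 6 assays were both below cycle 35 and higher there; miR-143 and miR-145 stood at 40 in both samples. Late-cycle drift of all low-level miRNAs stays open, since the median lay at percentile 99.33 of matched lists in this view, chosen after the data were seen, but at 91.1 for the 3 members detected in both samples, as planned. Whether ANGPTL1 or a chance difference between separately selected cell lines lies behind it also stays open, since there was 1 sample per group. A hypothesis for follow-up is that the cluster is transcribed more in the ANGPTL1 line, which may be checked in independent lines.

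miR-510 stood at cycle 29.25 in the control and showed no amplification in ANGPTL1 cells. If transcription of the whole miR-506 to miR-514 gene cluster in the control were its source, the neighbours would be detected too, but 0 of the 6 other measured members were below cycle 35 in the control, and 5 stood at 40 in both samples. An error of a single well, in either sample, may explain the gap and cannot be told apart from a change in miR-510 alone, because 1 value per sample is given for this assay.

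The log2 ratios of miR-422b and miR-422a were -2.81 and -1.16, and that of miR-378 was -0.44.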
